A study of Mus musculus with 6 samples.

How the data were processed

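Whole lungs of 6 mice were measured on Affymetrix MOE430A arrays, one array per mouse, 3 after saline and 3 after bleomycin (1 mg/kg in 50 µl of saline), all at day 14. Per the series' design text, the trachea and major airways were removed, the lobes were frozen and pulverised, and total RNA was extracted with Trizol, treated with DNase and converted to labelled cRNA. That text gives oropharyngeal delivery, while the source labels of the arrays name the intratracheal route, so the route is not settled here. Each array is described as a separate mouse, so the spread within a group includes that between animals. The letters A to F are unique to each array, so no array of one group is paired with one of the other.

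The deposited values are log2 expression values per probe set that the authors made with RMA and quantile normalization, per the series' design text and the submitters' processing notes. RMA summarises the probes of a probe set into one value. The software version, the background step and the chip definition are not given in the sources used here. The log base was settled from the values: the largest, 14.42, exceeds the 11.1 that a 16-bit scanner could give as a natural log and lies under its largest log2 value of 16. Sorted columns differed by up to 0.27 log2 units. Scanner files, detection calls and scan dates are not used here, so background, saturation and scan batch could not be examined, and no probe set was left out as undetected in the main test.

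The table held 22690 probe sets. The 64 control probe sets were left out, and 22626 were tested. Gene names came from GEO's platform annotation, with 20351 of the probe sets matched by Entrez ID to the RefSeq table of GRCm38.p6, which was used for names only. Of the tested probe sets 20380 had 1 gene symbol, 691 had several and 1555 had none listed. None was named from several symbols. A gene was read through the probe set with the highest mean over the 6 arrays, which gave 12393 genes. Of these, 4956 had several probe sets, as had 281 of the genes called, and 0 of the called genes had another probe set called in the opposite direction. Some genes of the fixed lists have no named probe set here and are not reported.

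Bleomycin was compared with saline in R 4.3.3 with limma 3.58.1 (lmFit and eBayes on the values as deposited, no covariates). P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. Adjusted p-values printed for a gene are limma's. Differences are bleomycin minus saline in log2 units, with the moderated standard error, and a fold is the power of 2 of that difference. A total of 32 gene lists (matrix, coagulation, signalling, cell types, cell states and other tissues) were tested with camera of the limma package, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The adjusted p beside a list is camera's. The count adjusted over the list alone repeats the adjustment among its members. The 3-prime minus 5-prime differences of the control probe sets were compared by an exact two-sided permutation test over 20 assignments. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

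The design, the lists, the alternatives and the rule for named genes were written before the data were examined. The rule took the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, and up to 4 called members with the largest differences from each list, or the largest difference where none passed. It also took a fixed set of genes of fibrosis, coagulation and lung cell types. Members named beyond it because a count was 5 or fewer were chosen after their values were seen: Col1a2, Plod3, Pmepa1, Tgfbr1, Tgif1, Bambi, Plin2, Itga8, Lgals3, Cyp2f2 and Zmat3.

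The fit was checked on simulated data with the real saline means of 22626 probe sets, for the comparison of bleomycin with saline. Spreads were drawn from the variance prior that limma fitted to these data, and noise was normal and independent between probe sets. The check therefore does not cover correlated genes or spreads unlike that prior. It recovered 78 of 100 probe sets changed by 1 log2 unit and 98 of 100 changed by 2, with 9 false calls among 185. The list test recovered 4 of 4 simulated lists shifted by 0.5, with 0 false calls, in data where genes vary independently. The alternatives were filters on dim probe sets, a trended robust variance prior, array weights, centring on ribosomal protein genes, repeated quantile normalization, other choices of probe sets, stricter thresholds, other list tests and leaving out each array in turn. Counts per list without saline B and without bleomycin D were added after seeing the data.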

Results

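The series asked how gene expression in the mouse lung differs during the fibrotic phase after bleomycin, a DNA-damaging chemotherapy drug whose delivery into the airways is a widely used model of lung fibrosis. RNA from homogenised lung was measured on 6 Affymetrix MOE430A arrays, one per mouse. The 3 saline mice are called A, B and C, and the 3 mice given bleomycin at 1 mg/kg are called D, E and F. All were killed at day 14, at an age of 8 to 10 weeks, and all are labelled as male wild-type C57BL/6J. The array median lay between 7.37 and 7.41 on the log2 scale on all 6 arrays. For arrays there is no read depth, and the number of arrays per group limits the precision.

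Arrays of the same group were close to each other. Pearson correlations across probe sets were 0.987 to 0.989 among the saline arrays, 0.986 to 0.995 among the bleomycin arrays, and 0.966 to 0.985 between groups. The first principal component held 55.4% of the variance. The saline arrays scored -28.6, -21.4 and -26.9 on it, and bleomycin D scored 44.3, against 12.9 for E and 19.8 for F. On saline B, the transcript of the inactive X chromosome, Xist, stood at 11.40, against 7.44 ± 0.26 (SD, n = 5) on the other arrays. The Y-linked gene Eif2s3y stood at 4.05 on saline B, against 7.66 ± 0.29 (SD, n = 5) on the others, so both genes go against its label. Among other Y-linked genes, Kdm5d was lower too (-2.64 log2 units from the mean of the other arrays). Uty (-0.47), Usp9y (0.34), Zfy2 (0.29) and Sry (0.07) differed by less. The difference between 3-prime and 5-prime control probe sets, a sign of RNA integrity, was 1.48 ± 0.30 in saline and 1.18 ± 0.12 in bleomycin lungs for Actb (SD, n = 3 each, exact two-sided permutation p = 0.3). For Gapdh it was 1.24 ± 0.32 and 0.96 ± 0.15 (SD, n = 3 each, exact two-sided permutation p = 0.3). The smallest p that 3 arrays against 3 can give in this test is 0.1.

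**Figure D1:**
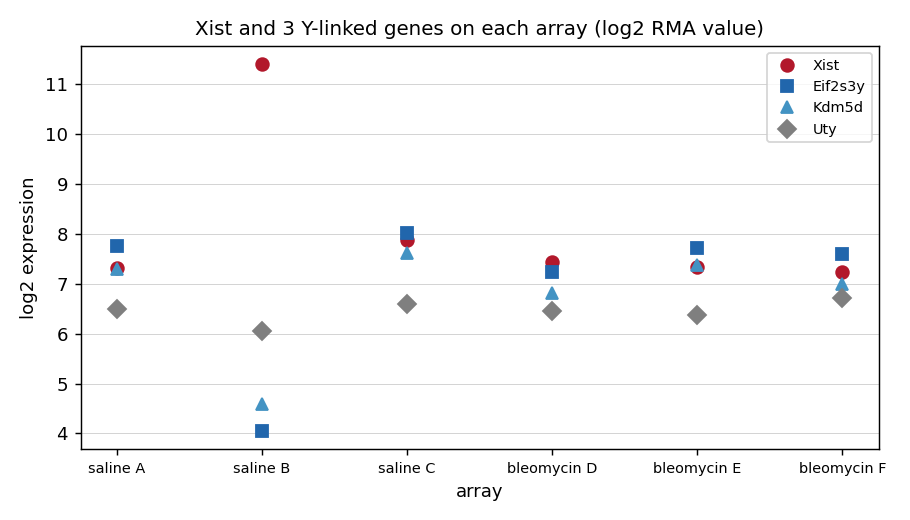
Log2 expression (vertical axis) of Xist and of the Y-linked genes Eif2s3y, Kdm5d and Uty on each of the 6 arrays (horizontal axis), one point per gene and array. Saline B has Xist at 11.40, Eif2s3y at 4.05 and Kdm5d at 4.58, while its Uty value of 6.06 lies closer to the mean of 6.53 on the other 5 arrays.

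Several genes of macrophages were among the 12 largest rises in the lung at day 14 after bleomycin. Mmp12, the macrophage elastase, rose 37.4-fold, from 6.00 ± 0.06 to 11.23 ± 0.13 log2 units (SD, n = 3 each, adjusted p = 3.05e-07). The complement recognition chains C1qb and C1qc rose 10.7-fold and 6.70-fold. Gpnmb, a glycoprotein of lipid-laden macrophages, rose 8.6-fold, Clec4n, which encodes the fungal receptor dectin-2, 7.93-fold, and the macrophage lysosomal protein Cd68 6.43-fold. Ms4a7 rose 5.96-fold and the chemokine Ccl9 rose 5.84-fold. The acute-phase gene Saa3 rose 6.83-fold and Tnc, which encodes the matrix protein tenascin C, rose 5.98-fold. Igkv9-120, an immunoglobulin kappa variable segment, rose 13.7-fold by its brightest probe set, and by 1.26 log2 units in the mean of its 3 probe sets, of which 1 passed the test. Arg1, the arginase of alternatively activated macrophages, rose 10.5-fold, but with a spread of 1.45 log2 units between the bleomycin lungs (SD, n = 3). Without bleomycin D the rise was 2.56 log2 units, against 3.39 with all arrays. Its adjusted p was 0.0186, and 0.0858 without saline A, 0.063 without saline C and 0.0582 with the trended robust prior.

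Falls were smaller than rises. Among the 12 largest falls were Bex2 (-1.66 log2 units), the peroxisomal thiolase Acaa1b (-1.63), the amino acid transporter Slc7a10 (-1.61), Gpr155 (-1.51), the transcription factor Klf15 (-1.5) and Igfbp3 (-1.5), which binds insulin-like growth factors. The others were the fibroblast growth factor carrier Fgfbp1 (-1.48), the metalloprotease inhibitor Reck (-1.42), the methyltransferase Inmt (-1.41), the aldehyde oxidase Aox3 (-1.40), Cys1 (-1.38) and the platelet receptor Clec1b (-1.37). Inmt, one of the brightest of them, fell from 13.30 ± 0.13 to 11.89 ± 0.60 (SD, n = 3 each, adjusted p = 0.0225). Cys1 rests on 1 of its 2 probe sets, the other of which differed by 0.06. The calls of Igfbp3 and Aox3 held in every fit with 1 array left out. Without saline A the adjusted p was 0.0513 for Bex2, 0.0758 for Acaa1b, 0.0586 for Slc7a10, 0.0655 for Gpr155, 0.0545 for Klf15, 0.061 for Fgfbp1, 0.0554 for Reck, 0.0863 for Inmt, 0.0634 for Cys1 and 0.0976 for Clec1b. Calls were also lost without saline B (Gpr155 0.0568, Inmt 0.0639, Cys1 0.0596, Clec1b 0.0948) and without saline C (Acaa1b 0.0543, Inmt 0.0614, Clec1b 0.114). The same was seen without bleomycin D (Gpr155 0.0591, Cys1 0.0715), E (Cys1 0.058, Clec1b 0.0679) and F (Acaa1b 0.0607, Gpr155 0.0725).

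In all, 694 of 12393 genes (5.60%) passed an adjusted p of 0.05 in limma, 458 higher and 236 lower after bleomycin. Of these, 195 rose and 45 fell at least 2-fold. At the level of probe sets, 1072 of 22626 passed, 744 higher and 328 lower. The 3 bleomycin arrays lay wholly above or below the 3 saline arrays for 3458 genes (27.9%, where chance gives 10% for a single gene), among them all 694 that passed. Genes vary together between arrays, so the 10% is no test of that share. A gene that passes with 3 arrays against 3 will seldom overlap, so the separation of the 694 adds no support. The counts were lower in every fit with a single array left out, and differed with the array. Without saline A, 163 genes were higher and 22 lower. They were 266 and 93 without saline C, 211 and 62 without bleomycin F, and 306 and 98 without saline B. Without bleomycin D they were 299 and 87, and without bleomycin E 385 and 165. Every such fit has fewer arrays and so less power. The counts alone therefore do not show how far the calls rest on particular mice.

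Matrix genes were described by 4 lists fixed in advance. Of 33 glycoproteins and proteoglycans, 11 rose and 0 fell (18 and 1 adjusted over the list alone). Eln, which encodes elastin, rose 4.70-fold (9.38 ± 0.38 to 11.62 ± 0.20, SD, n = 3 each) and Fn1, which encodes fibronectin, rose 3.8-fold (11.26 ± 0.05 to 13.19 ± 0.44, SD, n = 3 each). Of 28 matrix proteases and inhibitors, 13 rose and 0 fell (16 and 0 adjusted over the list alone). Besides Mmp12, they included the collagen-degrading protease Ctsk, 3.53-fold, and the metalloprotease inhibitor Timp1, 5.04-fold (adjusted p = 0.00586, and 0.0513 without saline A). Of 21 collagens, 5 rose (14 adjusted over the list alone) and 0 fell. These were Col1a1, 4.28-fold by 1 of its 2 probe sets (9.82 ± 0.69 to 11.91 ± 0.52, SD, n = 3 each, adjusted p = 0.0164), Col5a2, 3.22-fold, Col5a1, 2.28-fold, Col3a1, 2.17-fold (adjusted p = 0.0152), and Col1a2, 2.0-fold. Of 15 genes of collagen modification and cross-linking, 4 rose and 1 fell (7 and 1 adjusted over the list alone). Those that rose were Lox, 3.01-fold by 1 of its 3 probe sets (the lowest differed by 0.04 log2 units), Loxl1, 1.94-fold, Plod1, 1.71-fold, and Plod3, by 0.46 log2 units, and the one that fell was Pcolce2, which enhances procollagen processing, by 1.22.

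All 4 matrix lists passed camera with its preset correlation, with adjusted p = 1.36e-10 for the glycoproteins, 3.1e-16 for the proteases, 7.93e-09 for the collagens and 8.89e-05 for cross-linking. With an estimated correlation these were adjusted p = 0.255, 0.0713, 0.255 and 0.255. Fewer genes of these lists passed without saline A: 1 collagen rose, 0 cross-linking genes rose or fell, and 4 glycoproteins and 8 proteases rose. The list medians were little changed or higher there. They were 0.72 log2 units for collagens, 0.43 for cross-linking, 0.59 for glycoproteins and 0.59 for proteases. With all arrays they were 0.55, 0.44, 0.55 and 0.59. The lost calls come from a fit with fewer arrays and do not show a smaller matrix difference. Without bleomycin F, 0 collagens, 1 cross-linking gene and 7 glycoproteins rose, and the adjusted p of Col1a1 and Col3a1 was 0.0619 for each. The number of higher collagens was 3 without saline B and 3 without saline C, and 1 cross-linking gene was higher in each. Pcolce2 did not pass without saline A (0.111), B (0.101) or C (0.101), or without bleomycin E (0.0514). Without saline A the adjusted p was 0.0607 for Col3a1, 0.0714 for Col5a2, 0.0574 for Col5a1, 0.108 for Lox, 0.058 for Loxl1 and 0.0807 for Plod1. Col5a1 did not pass without saline B (0.057), saline C (0.065) or bleomycin F (0.0711), nor Col5a2 without bleomycin F (0.0514). Lox had an adjusted p of 0.0937 without saline B, 0.0705 without saline C and 0.091 without bleomycin F, and Plod1 passed only without bleomycin E.

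Of 35 measured genes of coagulation and fibrinolysis, 4 rose and 0 fell (6 and 2 adjusted over the list alone). F10, which encodes coagulation factor X, rose 3.0-fold, from 6.77 ± 0.23 to 8.36 ± 0.39 (SD, n = 3 each, adjusted p = 0.00553). It passed in 2 of its 3 probe sets, and the third differed by 0.40 log2 units. F7, which encodes factor VII, rose 2.82-fold, from 8.62 ± 0.16 to 10.11 ± 0.27 (SD, n = 3 each, adjusted p = 0.00214). The others were Procr, the endothelial protein C receptor, 2.91-fold, and the serine protease inhibitor Tfpi2, 2.27-fold. F3, which encodes tissue factor and starts the extrinsic pathway with factor VII, differed by 0.21 ± 0.20 log2 units (SE, adjusted p = 0.597). F2r, which encodes the thrombin receptor PAR1, differed by -0.48 ± 0.12 (SE, adjusted p = 0.0611). The calls of F10 and F7 held in every fit with 1 array left out, while without saline A the list had 2 genes higher, with an adjusted p of 0.0535 for Procr and 0.0797 for Tfpi2. Without bleomycin F, the adjusted p of Tfpi2 was 0.0627. The list as a whole did not pass camera (adjusted p = 0.104), and its median difference was -0.02, while its mean was 0.18. It passed without bleomycin E (adjusted p = 0.049) or F (0.0346), and when dim probe sets were left out (0.0189) or arrays were centred on ribosomal protein genes (0.0463).

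**Figure D2:**
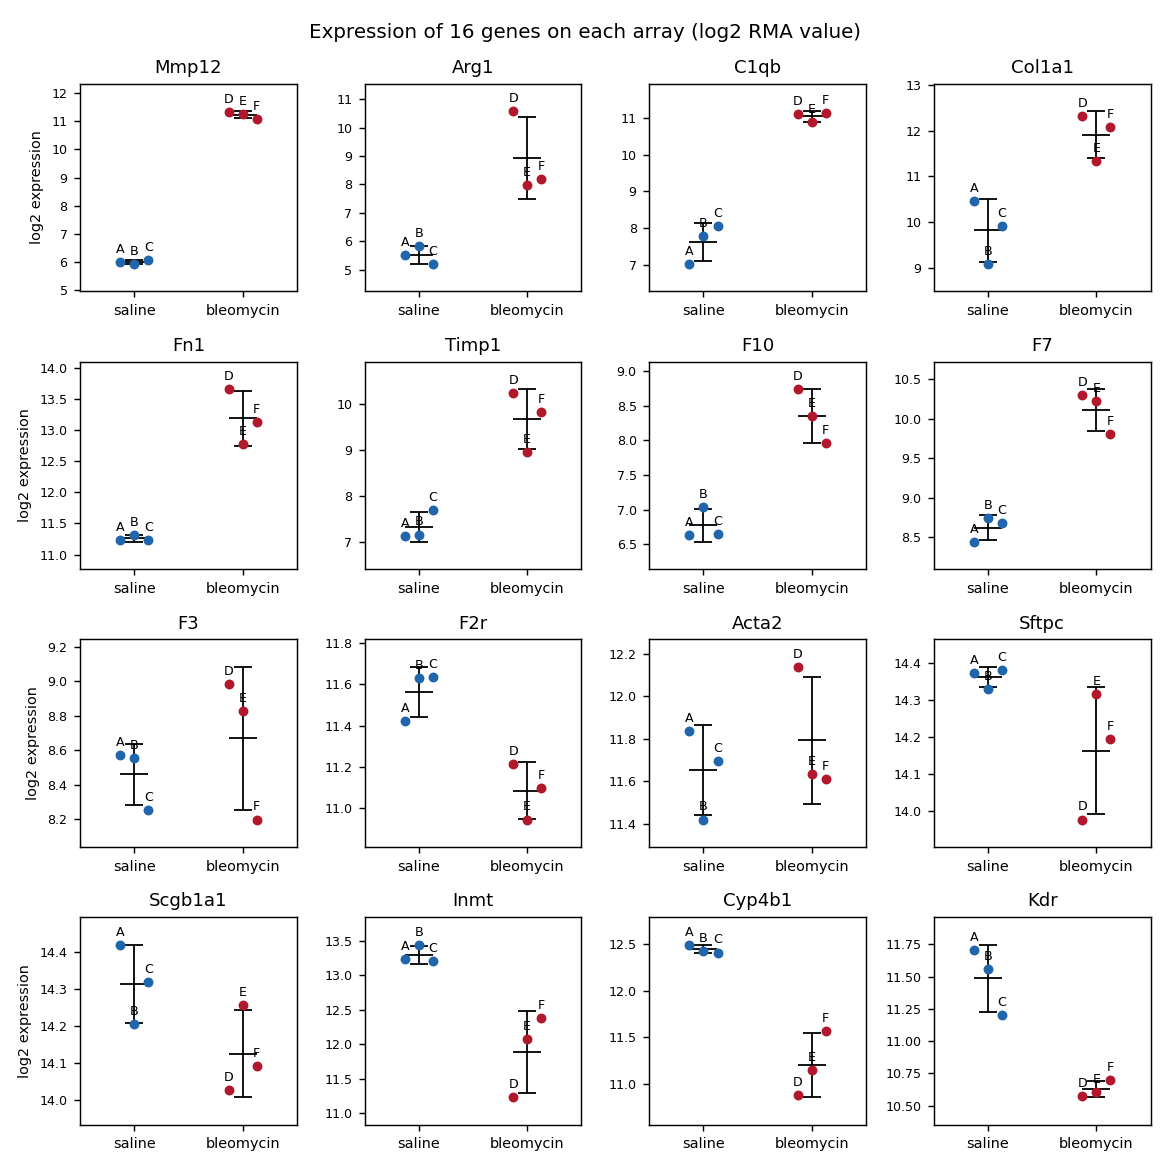
Log2 expression (vertical axis, with its own range in each panel) of 16 genes on the saline arrays A, B and C and the bleomycin arrays D, E and F (horizontal axis). Each point is an array, and the bars are the mean ± SD of 3. Bleomycin D has the highest value of Arg1, Col1a1, Fn1, Timp1 and F10 and the lowest of Inmt, Cyp4b1 and Sftpc, while F3, Acta2 and Sftpc did not pass the test.

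Genes of TGF-beta signalling moved in both directions: 5 of 29 rose and 3 fell (11 and 5 adjusted over the list alone). The ligand Tgfb3 rose 2.0-fold (8.24 ± 0.17 to 9.24 ± 0.14, SD, n = 3 each), and its call held in every fit with 1 array left out. Fstl1 rose 2.28-fold, and Pmepa1, Tgfbr1 and Tgif1 rose by 0.97, 0.87 and 0.57 log2 units. Smad6, an inhibitor of bone morphogenetic protein signalling, fell by 1.27, the ligand Bmp6 by 1.07 and the pseudoreceptor Bambi by 0.87. Tgfb1, the ligand most studied in fibrosis, differed by 0.36 ± 0.20 (SE, adjusted p = 0.34), and its responder Ccn2 by 0.55 ± 0.17 (SE, adjusted p = 0.108). The list passed camera (adjusted p = 0.00568, with adjusted p = 0.301 with an estimated correlation). Without saline A, 2 genes were higher and 1 lower, with an adjusted p of 0.0536 for Fstl1, 0.0574 for Smad6 and 0.113 for Bmp6. The number higher was 3 without saline B, saline C, bleomycin D or bleomycin F, where Fstl1 had an adjusted p of 0.0885, 0.105, 0.0836 and 0.105. Bmp6 had 0.0761 without saline B, 0.0735 without saline C and 0.0576 without bleomycin E.

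Of 30 fibroblast and myofibroblast genes, 2 rose and 4 fell (4 and 5 adjusted over the list alone). S100a4 rose 2.31-fold and Plin2, a coat protein of lipid droplets, rose by 0.71 log2 units. Inmt fell by 1.41, Limch1 by 0.85, the transcription factor Tcf21, which marks lipofibroblasts, by 0.80, and Itga8 by 0.63. Acta2, the smooth muscle actin of myofibroblasts, differed by 0.14 ± 0.17 (SE, adjusted p = 0.681), and without bleomycin D the difference was -0.03. Of 23 smooth muscle and pericyte genes, 1 rose, the pericyte gene Rgs5, 1.91-fold, by 1 of its 4 probe sets, and 0 fell (2 and 0 adjusted over the list alone). Neither list passed camera (adjusted p = 0.817 and 0.615). In the fibroblast list the 2 rises and 4 falls became 0 and 1 without saline A, 0 and 1 without saline B, and 0 and 2 without bleomycin F. They became 1 and 2 without bleomycin E, and 1 gene was higher without saline C or bleomycin D. S100a4 did not pass without saline A (adjusted p = 0.105) or B (0.0766), or without bleomycin D (0.0631) or F (0.093). Of the 6 fits with 1 array left out, Tcf21 passed only without saline C. Rgs5 did not pass without bleomycin F (adjusted p = 0.0553), where 0 genes of its list were higher and 1 lower.

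In the main test, genes of recruited and lipid-laden macrophages made up the list with the most changed members: 22 of 35 rose and 0 fell (26 and 0 adjusted over the list alone), with a median difference of 1.19 log2 units. The cell cycle list had more higher members adjusted over the list alone (33 of 44). With arrays centred on ribosomal protein genes the cell cycle list had 23 higher members, against 22 in the list of recruited and lipid-laden macrophages. Mmp12, C1qb, Arg1 and Gpnmb led this macrophage list. Between 18 and 22 genes of the macrophage list were higher in each fit with 1 array left out. Of 16 genes of resident alveolar macrophages, 3 rose and 1 fell (5 and 2 adjusted over the list alone). The lysosomal protease Ctsk, which stands in both lists, rose 3.53-fold, and the scavenger receptor Olr1 rose 2.97-fold. Plet1 rose 1.78-fold by 1 of its 2 probe sets (adjusted p = 0.0585 without saline A), and the keratin Krt79 fell by 1.37. Krt79 did not pass without saline A (adjusted p = 0.0773), B (0.0941) or C (0.111), or without bleomycin F (0.0928). Of 16 complement genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone), led by C1qb, C1qc, C1qa, 5.42-fold, and the receptor C3ar1, 4.55-fold. The 3 lists passed camera, with adjusted p = 1.03e-28, 0.00568 and 3.34e-09. With an estimated correlation these were adjusted p = 0.0713, 0.285 and 0.255.

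Some chemokine and antigen presentation genes were called higher as well. Of 44 chemokines and cytokines, 7 rose and 0 fell (15 and 3 adjusted over the list alone). Ccl9 rose 5.84-fold, Ccl8 5.61-fold, Ccl12 4.49-fold and Ccl17, which attracts T helper cells, 3.21-fold. Of 27 genes of antigen presentation and dendritic cells, 7 rose and 0 fell (12 and 0 adjusted over the list alone), among them Ccl17, the dendritic cell marker Cd83, 1.71-fold, and H2-DMa, 1.73-fold, which loads peptides on class II molecules. Of 29 interferon response genes, 3 rose and 0 fell (9 and 1 adjusted over the list alone), Cxcl10, 1.89-fold, Oas1a, 1.62-fold, and Ifit1, 1.57-fold. The 3 lists passed camera with adjusted p = 3.81e-07, 3.4e-09 and 7.11e-04, and with an estimated correlation these were adjusted p = 0.285, 0.255 and 0.404. Without saline A, 3 chemokines, 1 antigen presentation gene and 0 interferon genes were higher, and the adjusted p was 0.0634 for Ccl8, 0.0656 for Ccl12 and 0.0528 for Cd83. Antigen presentation genes higher were 2 without saline C or bleomycin D, and 1 without bleomycin F, where Cd83 had an adjusted p of 0.0581. With 1 array left out, H2-DMa passed only without saline B, Cxcl10 only without bleomycin E, and Oas1a and Ifit1 only without saline C. No interferon gene was higher without saline B, bleomycin D or bleomycin F, and 1 was without bleomycin E.

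Lymphocyte and granulocyte lists had between 0 and 3 called genes each. Of 31 T and natural killer cell genes, 0 rose and 0 fell in limma (0 and 0 adjusted over the list alone). The largest difference was that of the granzyme Gzma, -0.70 ± 0.28 log2 units (SE, adjusted p = 0.202). Of 21 B and plasma cell genes, 3 rose and 0 fell (5 and 0 adjusted over the list alone), all of them products of antibody-secreting cells: Jchain, 5.16-fold (9.72 ± 0.71 to 12.09 ± 0.27, SD, n = 3 each), Igha, 4.54-fold, and Iglv1, 3.85-fold by 1 of its 2 probe sets. Iglv1 did not pass without saline A (adjusted p = 0.0783), saline C (0.0512) or bleomycin F (0.0589). Of 21 neutrophil and mast cell genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone). Lcn2, an iron-scavenging protein also made by epithelium, rose 3.67-fold, and the integrin Itgam, shared with macrophages, rose 1.75-fold. Itgam did not pass without saline A (adjusted p = 0.0992) or B (0.0797), or without bleomycin D (0.0711) or F (0.0822). None of the 3 lists passed camera (adjusted p = 0.618, 0.115 and 0.777). The B and plasma cell list passed without saline B (0.0221), saline C (0.0277) or bleomycin D (0.0323) and with arrays centred on ribosomal protein genes (0.0487), and the T and natural killer list passed in the lower direction without saline A (0.0131).

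Of 22 genes of transitional epithelial cells, an intermediate state of alveolar repair, 5 rose and 0 fell (11 and 0 adjusted over the list alone). They were the cell cycle inhibitor Cdkn1a, 3.87-fold (9.66 ± 0.33 to 11.61 ± 0.05, SD, n = 3 each), Fn1, 3.8-fold, Sprr1a, 3.12-fold, Sfn, 2.27-fold, and Lgals3, by 1.02 log2 units. Of these, Cdkn1a also stands in the p53 list, Fn1 in a matrix list and Lgals3 in a macrophage list, so whole-lung values do not place them in the epithelium. The number higher was 5 or 6 in each fit with 1 array left out. Club and goblet genes were lower in part: 5 of 25 fell and 0 rose (8 and 0 adjusted over the list alone). These were the oxygenases Cyp4b1, by 1.25 (12.44 ± 0.04 to 11.20 ± 0.34, SD, n = 3 each), Fmo2, by 1.24, Fmo1, by 1.19, and Cyp2f2, by 0.66, and the carboxylesterase Ces1d, by 0.90. Scgb1a1, the club cell secretoglobin, differed by -0.19 ± 0.11 (SE, adjusted p = 0.379), near the top of the measured range at 14.31 ± 0.11 in saline lungs (SD, n = 3). Of 12 ciliated cell genes, 3 fell and 0 rose (5 and 0 adjusted over the list alone): Tppp3, by 1.02, Tekt2, by 0.53, and Dnah11, by 0.45. The 3 lists passed camera with adjusted p = 1.69e-08, 0.00149 and 0.00575, and with an estimated correlation these were adjusted p = 0.0713, 0.255 and 0.255. Without saline A, 1 club and 0 ciliated genes were lower, and the adjusted p was 0.126 for Fmo2, 0.0736 for Fmo1, 0.103 for Ces1d and 0.0862 for Tppp3. Club genes lower were 2 without saline B and 3 without saline C, bleomycin D or bleomycin F. Ciliated genes lower were 0 without bleomycin F and 1 without saline B, saline C or bleomycin D, and Dnah11 passed in none of the 6 fits. Fmo2 did not pass without saline B (0.0675), saline C (0.0976), bleomycin D (0.0607) or bleomycin E (0.0694), nor Ces1d without saline B (0.0721), saline C (0.0835) or bleomycin F (0.0893). Tppp3 did not pass without bleomycin D (0.0684) or F (0.091), and Tekt2 passed only without bleomycin D.

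Alveolar epithelial lists showed few calls. Of 25 type 2 cell genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone). These were the surfactant-processing protease Ctsh, 1.90-fold (11.97 ± 0.12 to 12.89 ± 0.16, SD, n = 3 each), and Retnla, 2.58-fold, which macrophages make too. Retnla did not pass without saline A (adjusted p = 0.124), saline C (0.118), bleomycin D (0.0983) or bleomycin F (0.116), and without bleomycin E 1 gene of the list was lower. Sftpc, which encodes surfactant protein C, differed by -0.20 ± 0.12 (SE, adjusted p = 0.369), near the top of the measured range at 14.36 ± 0.03 in saline lungs (SD, n = 3). Of 20 type 1 cell genes, 1 rose and 2 fell (1 and 7 adjusted over the list alone): Igfbp2 rose 1.95-fold, Limch1 fell by 0.85 and Hopx fell by 0.44. Ager, the type 1 cell receptor RAGE, differed by -0.19 ± 0.15 (SE, adjusted p = 0.499). The type 2 list did not pass camera (adjusted p = 0.618). The type 1 list did, in the lower direction (adjusted p = 0.0349, with adjusted p = 0.603 with an estimated correlation), but not without saline A (0.346) or bleomycin D (0.187), with the mean of all probe sets of a gene (0.0549) or in fry (0.232). Hopx passed in none of the 6 fits with 1 array left out, and Igfbp2 passed only without bleomycin D, so 1 gene was lower in each of those fits and 0 were higher, except 1 without bleomycin D.

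Endothelial genes were lower in part: 6 of 42 fell and 1 rose (12 and 1 adjusted over the list alone). The endothelin receptor Ednrb fell by 1.14 log2 units, the adrenomedullin co-receptor Ramp2 by 0.87 and the VEGF receptor Kdr by 0.86 (11.49 ± 0.26 to 10.63 ± 0.06, SD, n = 3 each), while Ackr1, the chemokine receptor of venules, rose 1.95-fold. Pecam1, a pan-endothelial marker, differed by -0.13 ± 0.17 (SE, adjusted p = 0.708), and by 0.06 without saline A. The list passed camera in the lower direction (adjusted p = 2.17e-05, with adjusted p = 0.285 with an estimated correlation). Without saline A, 0 genes of it passed, with an adjusted p of 0.0581 for Ednrb, 0.0584 for Ramp2, 0.0584 for Kdr and 0.103 for Ackr1. Ackr1 also did not pass without saline B (0.0707), saline C (0.0626) or bleomycin F (0.0504), nor did Kdr without bleomycin F (0.0508). Of 11 mesothelial genes, 1 fell, Igfbp6, by 1.32, and 0 rose (1 and 0 adjusted over the list alone, camera adjusted p = 0.907). Igfbp6 did not pass without saline A (0.104), saline C (0.0899) or bleomycin F (0.0542), and 2 genes were lower without saline B.

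Cell division genes were higher: 16 of 44 were higher and 0 lower (33 and 0 adjusted over the list alone), with a median of 0.68 log2 units. Ube2c, which marks proteins for degradation in mitosis, rose 3.63-fold, the kinase Cdk1 3.38-fold, the cyclin Ccnb2 3.38-fold and the proliferation marker Mki67 2.93-fold (7.33 ± 0.33 to 8.88 ± 0.31, SD, n = 3 each). Targets of p53 split: 4 of 29 rose and 1 fell (7 and 3 adjusted over the list alone). Cdkn1a rose 3.87-fold, Ccng1 2.46-fold and Phlda3 1.89-fold, Zmat3 rose by 0.87 and Igfbp3 fell by 1.5. The cell cycle list passed camera with adjusted p = 3.38e-20, and the p53 list with 0.0349; with an estimated correlation these were adjusted p = 0.255 and 0.285. Without saline A, 3 cell cycle genes were higher, Ube2c, Cdk1 and Mki67, and Ccnb2 had an adjusted p of 0.0586. The p53 list did not pass camera without saline B (0.0762), bleomycin E (0.118) or bleomycin F (0.0732), or with dim probe sets left out (0.0604), and its median was 0.03.

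Among stress and lipid genes, 4 of 32 antioxidant and glutathione genes rose and 0 fell (6 and 2 adjusted over the list alone). These were the metal-binding metallothioneins Mt2, 3.39-fold, and Mt1, 2.34-fold by 1 of its 2 probe sets, the haem oxygenase Hmox1, 2.24-fold (7.66 ± 0.26 to 8.82 ± 0.23, SD, n = 3 each), and Srxn1, 1.98-fold, by 2 of its 4 probe sets. Of 39 genes of fatty acid and sterol metabolism, 2 rose and 0 fell (2 and 0 adjusted over the list alone), the lysosomal lipase Lipa, 2.38-fold, and the lipoprotein lipase Lpl, 1.97-fold. Neither list passed camera (adjusted p = 0.119 and 0.145), though the antioxidant list did without saline A (0.0369) or bleomycin F (0.0306). Without saline A, 1 antioxidant gene was higher, with an adjusted p of 0.0724 for Mt2, 0.058 for Mt1 and 0.0932 for Srxn1. Without saline B it was 2, with 0.0507 for Mt1 and 0.0658 for Srxn1, and without bleomycin E 4 were higher and 3 lower. Mt1 did not pass without saline C (0.0629), nor Srxn1 (0.0508) or Lpl (0.0506) without bleomycin F.

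Lists of other tissues that a lung sample can hold were measured as well. Of 38 heart and skeletal muscle genes, 1 fell, the heart myosin Myh7, by 1.1 log2 units (6.91 ± 0.20 to 5.80 ± 0.13, SD, n = 3 each), and 0 rose (1 and 0 adjusted over the list alone). That list passed camera in the lower direction (adjusted p = 9.07e-04, with adjusted p = 0.285 with an estimated correlation), and 2 of its genes were lower without saline B. Of 20 cartilage, adipose and thymus genes, 1 fell, the adipose hormone Retn, by 0.46, and 0 rose (1 and 0 adjusted over the list alone, camera adjusted p = 0.338), and Retn passed in none of the 6 fits with 1 array left out. Of 13 blood cell and platelet genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.119), and the platelet chemokine Ppbp differed by -1.45 ± 0.45 (SE, adjusted p = 0.11). Without saline A the blood list passed camera in the lower direction (0.0499). Of 33 ribosomal protein genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.502), with a median of 0.01. The largest difference there was that of Rpl27a, -0.69 ± 0.39 (SE, adjusted p = 0.35), and without saline B the list passed camera in the higher direction (0.0114).

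**Figure D3:**
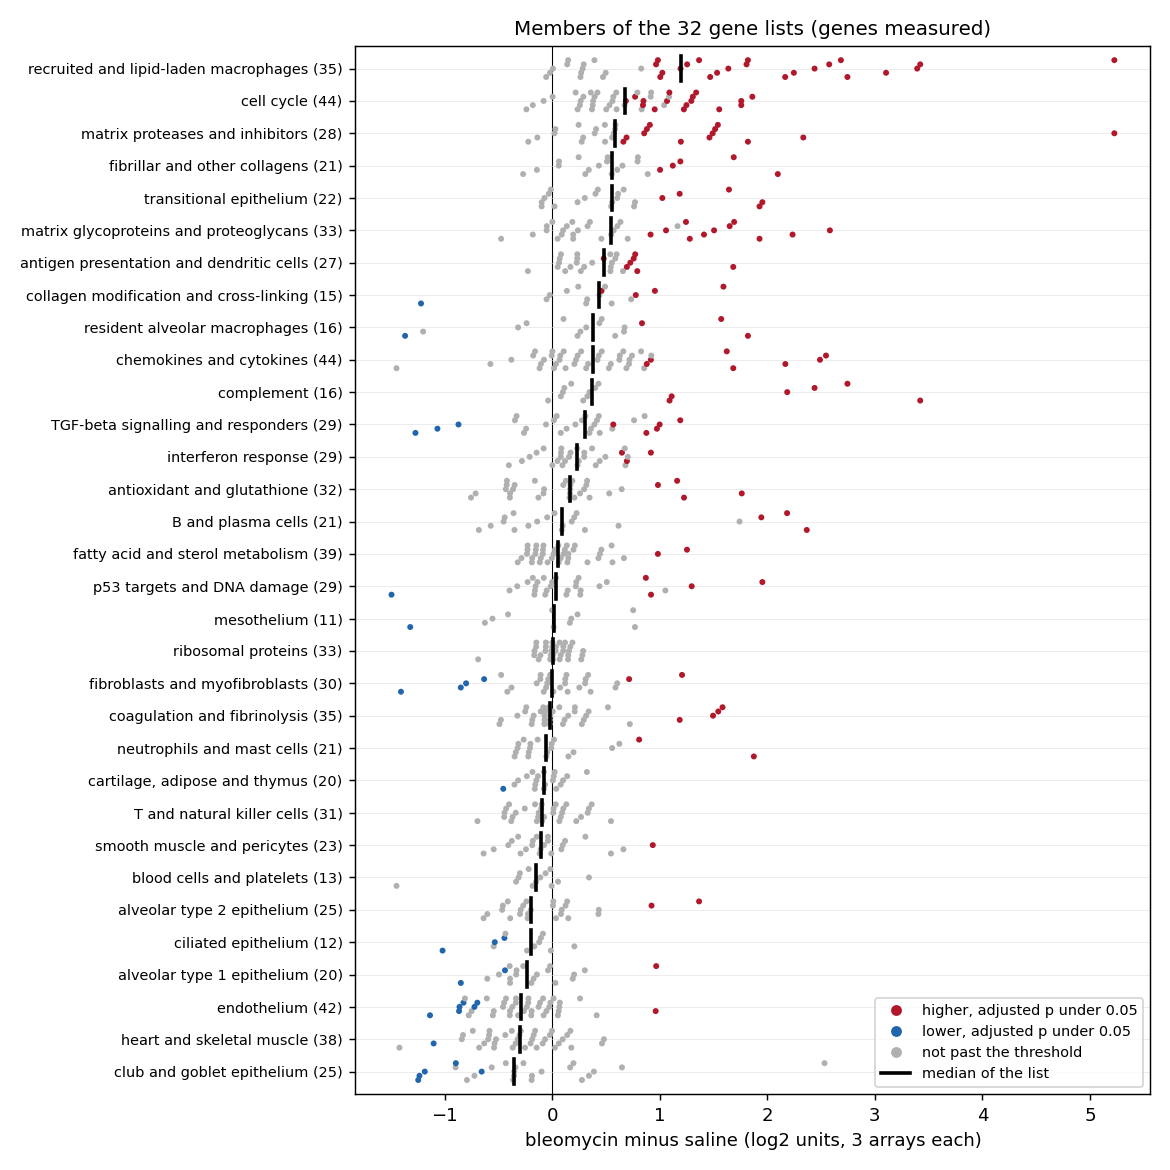
Difference between bleomycin and saline lungs in log2 units (horizontal axis) for each measured member of the 32 gene lists (vertical axis, with the number of genes measured), from 3 arrays each. Points are genes, red where higher and blue where lower at an adjusted p under 0.05, grey where not past the threshold, and black bars are list medians. The macrophage list has the highest median, 1.19, and the club and goblet list the lowest, -0.35.

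With its preset correlation, camera put 19 of the 32 lists past the threshold, and with an estimated correlation 0, where the lowest adjusted p was 0.0713. The tool fry, which asks whether the genes of a list move on balance one way, put 15 lists past it, 14 of the 19 and the fatty acid and sterol list (adjusted p = 0.0329). Besides type 1 cells, the lists it did not keep were TGF-beta signalling (0.0844), interferon response (0.139), endothelium (0.0688) and heart and skeletal muscle (0.0735). The 9 other splits of the 6 arrays into 3 and 3 put 10 to 20 lists past the threshold in camera with the preset correlation, and 0 genes in limma, against 694 genes in the real split. Each of these splits sets 2 arrays of one treatment and 1 of the other against the rest, so it keeps part of the treatment difference. It also puts treatment differences into the spread within its groups, which by itself lowers the number of genes that pass. The 0 genes there therefore lend no support to the 694. The transitional epithelium list had an estimated correlation of -0.021, which is under the preset 0.01. Its adjusted p in camera still went from 1.69e-08 to 0.0713. The size of the correlation therefore does not account for every such loss, and the 0 does not show that correlated genes undid the lists. What else differs between the settings was not tested. As the list test depends on the setting used, each list is given first by its gene counts.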

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

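All alternatives for the counts below were planned. The counts of genes higher and lower stayed within 1.5 times of 458 and 236 under both filters on dim probe sets, the trended robust prior, array weights (599 and 341), ribosomal protein centring, repeated quantile normalization (407 and 310), and both other choices of probe sets. At an adjusted p under 0.01 they were 143 and 20, with 236 probe sets, and with at least a 2-fold difference 195 and 45, with 361 probe sets, both by construction stricter. With 1 array left out, genes higher ranged from 163 (without saline A) to 385 (without bleomycin E), genes lower from 22 to 165 and probe sets from 284 to 901 with the same arrays, from fewer arrays per fit. Of 102 named genes past the threshold, 59 lost their call without saline A, 36 without bleomycin F, 27 without saline B, 26 without saline C, 19 without bleomycin D and 14 without bleomycin E.

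Of the 19 lists past the threshold in camera, 0 stayed past it with an estimated correlation, 14 in fry, and 18 or 19 with 1 array left out or under the other alternatives. Lists that passed only in the alternative brought the totals to 15 in fry and to 19 to 21 with 1 array left out; the cause was not tested. Directions reversed for lists that passed in neither setting. The direction is that of camera or fry and need not follow the sign of the median, so a median given here can keep its sign. The fibroblast list had a median of -0.020 with dim probe sets left out and -0.0057 in fry, and -0.056 to 0.098 with 1 array left out. The neutrophil and mast cell list had -0.095 with dim probe sets left out and -0.16 to 0.0019 with 1 array left out. The other ranges with 1 array left out were -0.12 to -0.035 for smooth muscle, -0.17 to 0.016 for T and natural killer cells, -0.26 to 0.048 for type 2 epithelium, -0.092 to 0.11 for mesothelium and -0.038 to 0.11 for ribosomal proteins. Acta2 ranged from -0.030 (without bleomycin D) to 0.24, and Pecam1 from -0.29 to 0.056 (without saline A). The cause was not tested. Arrays in these files carry no background measure, so how far dim probe sets understate a change is open.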

Other observations

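Of the tests in this part, the counts over splits of the arrays and the test of Y-linked genes on saline B were chosen before their results were seen (the reading of the latter was changed after), and all others after.

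Genes that share the letters of their symbol were looked at as families, 226 families of at least 8 genes in each direction, by Fisher's exact test with Benjamini-Hochberg adjustment. Among the genes that rose, 5 families were over-represented. They were the Cd surface antigens, with 17 of 80 (adjusted p = 1.78e-06, among them Cd14, Cd53, Cd68 and Cd84), and the C-type lectins, with 6 of 20 (adjusted p = 0.0139), Clec4a2, Clec4d, Clec4n, Clec5a, Clec7a and Clec11a, while Clec14a and Clec1b fell. The Lgals symbols had 4 of 9 (adjusted p = 0.0301), the galectins Lgals1, Lgals3 and Lgals9, and Lgals3bp, which encodes a galectin-binding protein rather than a galectin. The others were the CC chemokines, with 5 of 18 (adjusted p = 0.035), Ccl6, Ccl8, Ccl9, Ccl12 and Ccl17, and the matrix metalloproteases, with 5 of 18 (adjusted p = 0.035), Mmp2, Mmp3, Mmp12, Mmp13 and Mmp14. Both scaling alternatives gave 15 Cd genes, 6 or 7 lectins, 3 or 4 Lgals genes, 6 chemokines and 5 metalloproteases. Without saline A the 5 families had 9, 4, 3, 3 and 4 genes higher, and the Cd genes were 11 without saline C or bleomycin D and 7 without bleomycin F. Genes are not independent replicates, so these p-values describe the list of calls.

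Of 19 immunoglobulin genes measured, 5 rose (Igkv9-120, Jchain, Igha, Iglv1 and Igkv8-30) and 0 fell. More B cells in the lung would raise their surface and transcription factor genes too, but 0 of 9 such genes passed, and their median difference was -0.35 (Ms4a1 -0.44, Cd79a -0.22, Cd79b -0.45). The mean of these 9 genes relative to saline was -0.63 on bleomycin D, -0.24 on E and 0.06 on F. On saline A, B and C it was -0.38, 0.35 and 0.03, a range that includes E and F. A small rise or fall of B cells can therefore not be told from the spread between mice. More antibody-secreting cells, or more transcript in each, may remain as a candidate explanation that was not tested further.

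Some clock genes differed between arrays of the same group. The transcription factor Dbp stood at 11.75 and 11.48 on saline A and B but at 6.55 on saline C, and at 8.81, 9.77 and 6.53 on bleomycin D, E and F. Relative to the mean of saline A and B, saline C differed by -2.05 log2 units for Nr1d2, -1.52 for Per3 and 2.32 for Arntl, genes picked after their values were seen. It differed less for others, by -0.08 for Bhlhe41, 0.22 for Npas2, -0.32 for Cry1 and 0.55 for Clock, and no test was made of saline C. In limma, 0 of the 15 clock genes looked at passed between groups (6 had an unadjusted p under 0.05), and the lowest adjusted p was 0.0705, of Per3. All 3 bleomycin arrays lay under saline A and B for 9 of the 15, Dbp, Tef, Hlf (bleomycin minus saline -1.27), Nr1d1, Nr1d2, Per1, Per2, Per3 (-1.65) and Cry2. Saline C was left out of this comparison after its values were seen. For Dbp and Tef (10.09 on C) it lay within the range of the bleomycin arrays. The share of all genes with this pattern was not counted, so the pattern does not show a difference between the groups. Whether lungs were collected at different times of day was not tested.

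Saline B is labelled male, but its Xist was 3.96 log2 units above and its Eif2s3y -3.62 units from the mean of the other 5 arrays. A male sample mixed with female RNA would keep part of the Y-linked signal, but Eif2s3y lay at the 1.55 percentile of saline B. A bleomycin-treated lung in its place is argued against by a mean response of 0.124 of that of the bleomycin arrays, where the lowest single bleomycin array had 0.903; that value missed a first bound of 0.1, and the comparison with single arrays was added afterwards. A female lung may be the source: Kdm5d was also lower (-2.64), but Sry (0.067) and Uty (-0.47), both above the 25th percentile on the other arrays, missed the drop of 1 unit set in advance, which counted against a female lung as first written, and Usp9y (0.34) and Zfy2 (0.29), under that percentile, were not lower. Only after this result was it noticed that Xist itself exceeds that floor on the 5 other arrays (46.9 percentile or higher), so the floor does not show that a probe set detects its gene; on this later reading the question stays open, as does whether sex changes any value here.

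Bleomycin D stood furthest from saline. RNA degradation would raise its 3-prime minus 5-prime difference, but that of Gapdh was the lowest of the 6 arrays (0.81), and that of Actb (1.23) lay inside the range of the others. Poor hybridisation would move the spike-in controls, whose mean on D (9.29) lay between 9.09 and 9.54, the range of the others. Over 386 genes called without D, its median response was 1.21 times that of E and F. The same ratio to the other bleomycin arrays was 0.73 for E and 0.89 for F, each over the genes called without it. The larger ratio of D restates its place on the first principal component, which parts the groups. A larger response of this mouse therefore stays open with no support over other causes. A low 18S control signal on D (8.24, against 9.64 to 11.01 on the others) is left unexplained, and other differences of tissue or handling were not tested.

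Endothelial, club and ciliated genes were lower in part, as dilution by incoming cells could give. Dilution alone would lower alike all markers that incoming cells lack, but over the 73 members of these 3 lists that stand in no other list, with a common shift of -0.31, the differences spread by an SD of 0.34 beyond their standard errors. A spread as wide came in a share of 1e-04 of simulated draws, the smallest share that 10000 draws can give. Compression of bright or dim signals would narrow this to markers outside the middle range, but the 49 with a mean between 8 and 12 spread by 0.38, with the same smallest share. The 73 include Ackr1, which rose, and the draws gave all probe sets a common shift with independent errors. Unlike background or response of single probe sets was not simulated. The test therefore cannot tell dilution together with a few changed markers from other causes. A change within these cell types, or in their shares, after bleomycin stays open as a hypothesis, and dilution of part of the shift is not excluded. Whether incoming cells express some of the 73 markers was not tested.

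Over the 10 splits of the 6 arrays into 3 and 3, the real one gave 694 genes and the highest other gave 0, so 1 split gave as many. For lists in camera with the preset correlation the real split gave 19 and the highest other 20, and 3 splits gave at least as many. That other split set saline A and B with bleomycin E against the rest, and all the others put at least 10 lists past the threshold. Each of them keeps part of the treatment difference, since 2 arrays of one group stand with 1 of the other, so lists passing there do not show where the signal comes from. The same mixing widens the spread within the groups of such a split, so the 0 genes there lend no support to the 694. With 10 splits a share under 0.05 cannot be reached in either case.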
